A study of Mus musculus with 6 samples.

How the data were processed

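Messenger RNA was sequenced from the inguinal white adipose tissue, the subcutaneous fat pad of the groin, of mice that lacked the insulin-like growth factor 1 receptor gene Igf1r in adipocytes and of littermate controls. Per the labels' protocols, mice with a floxed Igf1r gene were crossed with mice that carry Cre recombinase under the adiponectin promoter (Adipoq-Cre). The knockout group is called AdIGF1RKO and the floxed littermates without Cre are called Flox. All mice ate a diet with 10% of its energy from fat for 24 weeks and were fasted overnight before the tissue was taken, per the labels' protocols. Each group had 3 libraries, which the labels number 1 to 3, and the titles speak of mice, not of repeated libraries of the same mouse. Libraries were stranded and made from polyadenylated RNA, per the labels' protocols. The submitters' processing notes name the genome build GRCm39. The aligner, the counting tool, the gene annotation and the filter behind the table are not given in the sources used here. The reference annotation at hand is of an earlier build, so no coordinates are printed.

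The authors deposited 1 table of 14861 genes by 6 libraries, whose name calls the values FPKM. The values behave otherwise. In each library every value, within a rounding tolerance of 0.5, was a whole number of reads times 1000000000 divided by a single number for that library, and this held for 100.0% of the values. The deposited signal is therefore a read count scaled per library and not divided by gene length. The divisor was a multiple of 1000 in each library, from 39206000 in Flox 3 to 81802000 in AdIGF1RKO 1. It was not the sum of the recovered reads, which lay between 60617147 and 70695527. Recovered reads over the divisor ranged from 0.864 in AdIGF1RKO 1 to 1.55 in Flox 3. The table holds no value of 0 and its lowest entry is 1 read, so genes without reads in some library are not analysed here.

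The test fixed before the data were examined was limma on log2(FPKM + 1) of the values as deposited, with median-ratio scaling as an alternative. Because the values were not FPKM and their divisors disagreed with the read totals, these 2 scalings were exchanged. The exchange was decided after the library totals, the divisors and the deposited values of Igf1r, Apln, Lep and Adipoq had been seen, and before any test was fitted. With the values as deposited, the median log2 difference of all genes between AdIGF1RKO and Flox was -0.16 and 17.7% of genes were higher in AdIGF1RKO. With median-ratio scaling the median was -0.02 with 45.5% of genes higher, and with all libraries scaled to equal sums it was 0.09 with 70.4% higher. All differences below are relative to the median-ratio scaling unless another is named.

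The recovered reads were divided by median-ratio size factors, from 0.731 in Flox 3 to 1.17 in AdIGF1RKO 1, and expressed relative to a library of geometric mean size. These values are counts per 1000000 reads of such a library and are called scaled CPM. A single read corresponds to between 0.013 and 0.021 scaled CPM. Genes with a mean of at least 1 over the 6 libraries were tested, which kept 12993 genes and left out 1868. The group difference was fitted with limma (version 3.58.1, R version 4.3.3) on log2(value + 1) with an intensity trend in the empirical Bayes step. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The log2 differences are on the log2(value + 1) scale, which understates the change of genes with low values. Unadjusted p-values in the text come from this limma model unless stated otherwise. Fewer than 10 libraries were available, and an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, nor below 0.25 with exchanges only within same-numbered pairs. The test within pairs was added after seeing the data.

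Before the data were examined, 40 gene lists for adipose pathways and cell types were fixed. Of these, 37 had at least 5 tested genes and were tested with camera, which ranks a list against all other tested genes, with a preset inter-gene correlation of 0.01. The same lists were tested with an estimated correlation and with fry as alternatives. The named genes followed a rule fixed at the same time. It takes Igf1r, then Apln, Aplnr and Ctnnb1 from the series title. It then takes the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups. Where fewer than 5 genes pass in a direction, the 12 places are filled with the largest differences among genes with an unadjusted p under 0.01 and no overlap, passing over predicted genes, clones, pseudogenes and antigen receptor segments. In each list described in detail, the rule takes up to 4 members with the smallest unadjusted p. Because no gene passed, every gene named by the third part came from the filling step. Some genes that the rule takes are not reported here.

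The same 3 replicate numbers occur in both groups. The labels do not say what a number marks. The deviations of same-numbered libraries from their group means correlated across genes at 0.35 for number 1, 0.35 for number 2 and 0.83 for number 3, so the numbers were treated as pairing the samples in an alternative fit with the number as a block. Flox 2 correlated more strongly with AdIGF1RKO 1, at 0.70, than with its own number. Flox 3 and AdIGF1RKO 3 were also the libraries richest in skeletal muscle RNA, so the 0.83 cannot show that a number marks a pair. No 2 libraries agreed within sampling noise, since the chi-square per degree of freedom over all genes was at least 55.3 for every pair.

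Further alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5, quantile normalization, no trend, a robust fit, array quality weights and each library left out in turn. Added after seeing the data were edgeR (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, a covariate for skeletal muscle RNA, and the omission of both libraries with the most such RNA. The muscle covariate is the mean log2 value of the skeletal muscle marker list. On simulated counts for the 12993 tested genes of the AdIGF1RKO and Flox comparison, with the trended dispersion of the real libraries and 200 genes changed, the limma steps called 15% of genes changed by a log2 size of 1 and 93% of genes changed by 2, with 3 false calls. With gene-wise dispersions they called 16% and 86%, with 10 false calls. These shares hold for 200 genes changed together, since the Benjamini-Hochberg cut eases as more genes change. Where few genes change they would be lower, so an absence of calls would not show that changes of 2 are absent. In simulated libraries without any change, 0 of 37 lists passed camera, and with the cholesterol synthesis list shifted by 0.5 only that list passed. In the real libraries the estimated inter-gene correlation was 0.34 for cholesterol synthesis, 0.84 for oxidative phosphorylation and 0.95 for skeletal muscle markers. At least 12 lists passed in 6 of 10 splits of the real libraries into 3 and 3, the real split included. The simulation therefore does not show that camera's chance calls are controlled in the real libraries. Python 3.11.15 was used to recover the reads and draw the plots.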

Results

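The data are 6 libraries of polyadenylated RNA from the inguinal white fat of mice, 3 from Flox controls and 3 from AdIGF1RKO mice, in which Igf1r was deleted by Cre recombinase expressed in adipocytes. Between 60617147 and 70695527 reads per library were assigned to the 14861 genes of the table, and the median gene had between 755 and 1120 reads. The comparison of both groups asks which transcripts of this fat depot differ when adipocytes lose the receptor, under a diet low in fat. The series title names β-catenin and apelin, so the genes of these were read out first after Igf1r.

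Igf1r itself, the floxed gene, had 6.26 ± 0.343 scaled CPM in Flox (SD, n = 3) and 5.41 ± 0.639 in AdIGF1RKO (SD, n = 3). The groups overlapped: the Flox libraries had 6.44, 6.47 and 5.86, and the AdIGF1RKO libraries had 6.11, 5.27 and 4.85. The log2 difference was -0.18 with a standard error of 0.12 and a 95% interval from -0.48 to 0.12, and it did not pass the limma test (adjusted p = 0.998). Each value rests on 283 to 471 reads, and the tissue also holds cells in which Cre is not expressed. The labels do not say which part of the gene is removed, and the counts cover the gene as a whole. With the values as deposited, where the median of all tested genes was -0.17, the log2 difference was -0.33, which did not pass either (adjusted p = 0.724).

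Apln, which encodes the secreted peptide apelin, had 2.93 ± 0.586 scaled CPM in Flox and 8.47 ± 1.04 in AdIGF1RKO. All 3 AdIGF1RKO libraries lay above all 3 Flox libraries, at a ratio of means of 2.89 and a log2 difference of 1.27 with a standard error of 0.16. Its unadjusted limma p of 0.000158 was the smallest of all genes, and it did not pass adjustment over all 12993 genes (adjusted p = 0.998). Aplnr, the apelin receptor gene, had 12.2 ± 1.09 in Flox and 18.9 ± 3.90 in AdIGF1RKO, again without overlap. Aplnr had a log2 difference of 0.57 with a standard error of 0.16. It did not pass the limma test (adjusted p = 0.998) or DESeq2 (adjusted p = 0.354). Ctnnb1, which encodes β-catenin, had 381 ± 11.1 in Flox and 425 ± 25.7 in AdIGF1RKO, with a log2 difference of 0.15 and a standard error of 0.09. The 3 AdIGF1RKO values of Ctnnb1 lay above the Flox values with median-ratio scaling. Its log2 difference was 0.28 with libraries scaled to equal sums, 0.24 with quantile normalization and -0.01 with the values as deposited, against that median of -0.17, and it did not pass with any of these.

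**Figure D1:**
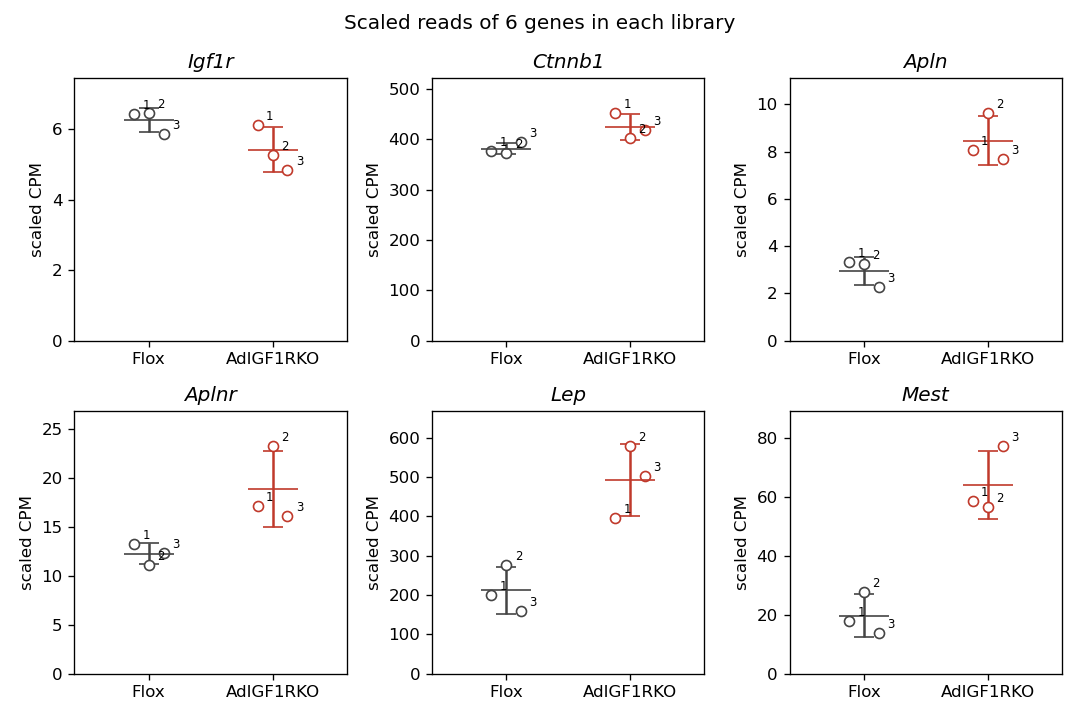
Scaled CPM (vertical axes, from 0) of Igf1r, Ctnnb1, Apln, Aplnr, Lep and Mest in the Flox and AdIGF1RKO libraries, where circles are libraries with their replicate number, wide bars are means and error bars are the SD of 3 libraries. The groups overlap for Igf1r, and the 3 AdIGF1RKO libraries lie above the 3 Flox libraries for the other 5 genes.

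Across the transcriptome, 0 of 12993 genes passed the limma test at an adjusted p under 0.05, and the smallest adjusted p was 0.998. By chance 650 genes would be expected at an unadjusted p under 0.05, with a wider spread around that number where genes are correlated. There were 385, of which 238 were higher and 147 lower in AdIGF1RKO. That split depends on the scaling: of 520 such genes with the values as deposited 59 were higher, and of 244 with all libraries scaled to equal sums 220 were higher. The count was 241 without AdIGF1RKO 2, 582 with the replicate number as a block (270 higher) and 857 with array quality weights (430 higher), the last above the number expected by chance. The groups did not overlap for 8.27% of genes, against the 10% that chance gives for 3 against 3. edgeR's quasi-likelihood test on the recovered reads also called 0 genes, with 378 at an unadjusted p under 0.05. DESeq2 called 23 genes, 17 higher and 6 lower, with 494 at an unadjusted p under 0.05. It was the only test on all 6 libraries to call any gene at an adjusted p. Both count tests were added after the data had been seen. Without Flox 1, limma called 1 gene, Aldh1a7.

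Among genes with an unadjusted p under 0.01 and no overlap of the groups, the 12 with the largest differences towards AdIGF1RKO, none of which passed the limma test, included Mest and Lep. Mest, an imprinted gene whose level in fat is known to vary with fat mass, had 19.7 ± 7.28 scaled CPM in Flox and 64.1 ± 11.5 in AdIGF1RKO (log2 difference 1.70, standard error 0.26). Lep, which encodes the adipocyte hormone leptin, had 212 ± 59.5 and 493 ± 92.5 (1.23, standard error 0.23). Sfrp5, a secreted Wnt inhibitor, had 18.0 ± 5.47 and 35.6 ± 4.48. Npr3, the natriuretic peptide clearance receptor, had 127 ± 36.7 and 234 ± 40.7. Tuba1a, an alpha-tubulin, had 442 ± 52.6 and 895 ± 220. Prnd had 2.47 ± 0.949 and 8.40 ± 1.26, and Zfp949, a zinc finger gene, had 11.5 ± 2.04 and 24.9 ± 3.75. Others in this direction were Slc5a7, Syt12 and Fhit, with log2 differences from 0.82 for Fhit to 1.30 for Slc5a7. Apln was also among these 12 genes. For each of them the 3 AdIGF1RKO libraries lay above the 3 Flox libraries, and the unadjusted p was between 0.000158 for Apln and 0.00917 for Npr3. Of the genes named here, DESeq2 called Apln, Mest, Prnd, Slc5a7, Lep, Zfp949, Tuba1a and Sfrp5, and it did not call Npr3, Syt12 or Fhit.

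In the other direction the largest differences among genes with an unadjusted p under 0.01 and no overlap were in the major urinary protein genes, which encode secreted lipocalins. Mup11 had 159 ± 81.9 scaled CPM in Flox and 48.5 ± 18.6 in AdIGF1RKO, Mup18 had 910 ± 562 and 282 ± 68.7, and Mup22 had 2550 ± 1561 and 820 ± 183. These genes are near-identical copies, so how their reads were divided among them is uncertain. Pon1, the paraoxonase gene, had 42.7 ± 7.99 and 25.3 ± 4.72. Gna15, a G protein alpha subunit, had 4.23 ± 0.449 and 2.31 ± 0.0565. Clcc1, a chloride channel of the endoplasmic reticulum, had 64.9 ± 8.77 and 46.6 ± 0.119. Eif2s3y, on the Y chromosome, had 81.1 ± 6.37 and 59.0 ± 4.63. The others were Ica1l, Fam185a, Alg6, Prdm9 and Zfp579, with log2 differences from -0.55 for Ica1l to -0.40 for Zfp579. The 12 genes had unadjusted p-values from 0.00172 for Gna15 to 0.00977 for Fam185a and did not pass the limma test. DESeq2 called Mup11, Mup18, Mup22 and Gna15 among them.

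The libraries differed in skeletal muscle RNA. The skeletal muscle markers took 13.2% of the reads in Flox 3 and 4.78% in AdIGF1RKO 3. They took 0.925% in Flox 1, 0.112% in Flox 2, 0.0572% in AdIGF1RKO 1 and 0.290% in AdIGF1RKO 2. Of 19 tested markers 18 were lower in AdIGF1RKO, with a median log2 difference of -1.51, and the list did not pass camera (adjusted p = 0.0619). It passed with the replicate number as a block (adjusted p = 0.00051) and with libraries scaled to equal sums (adjusted p = 1.8e-06). The list also passed without Flox 2 (median -3.20, adjusted p = 1.1e-05), without AdIGF1RKO 3 (-3.15, adjusted p = 1.9e-07) and without both Flox 3 and AdIGF1RKO 3 (-1.41, adjusted p = 0.000362). The same held with quantile normalization (adjusted p = 0.0135) and a mean of at least 5 (adjusted p = 0.0232). Its median was -0.01 without AdIGF1RKO 1 and 0.34 without Flox 3, and it had an adjusted p = 0.932 with an estimated correlation. The first principal component held 74.1% of the variance and placed Flox 3 and AdIGF1RKO 3 at one end. AdIGF1RKO 2 stood apart in genes of lipid-laden macrophages: Mmp12 had 121 scaled CPM there and at most 13.3 in the other 5 libraries, Spp1 had 182 and at most 12.9, and Trem2 had 62.8 and at most 12.1. These 3 genes were chosen after their values were seen. Without Flox 3, without AdIGF1RKO 3, without both, and without AdIGF1RKO 2 limma called 0 genes each time.

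**Figure D2:**
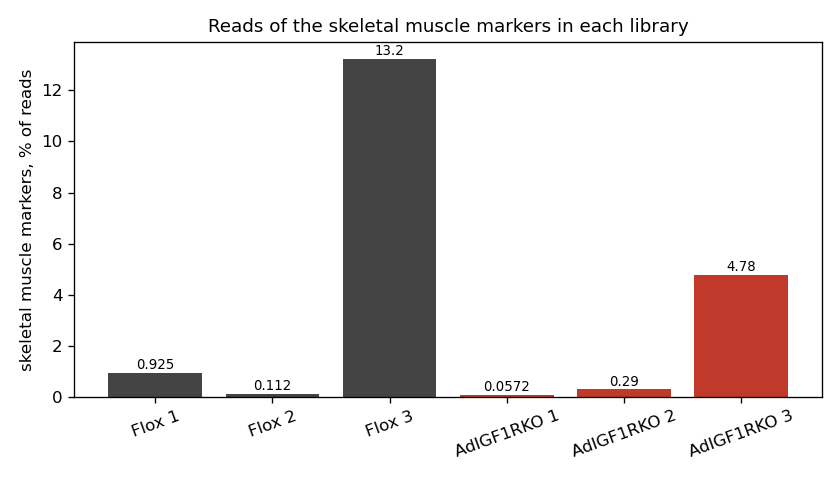
Share of all recovered reads, in percent (vertical axis, from 0), that fell on the skeletal muscle markers in each of the 6 libraries. The bars reach 13.2% in Flox 3 and 4.78% in AdIGF1RKO 3, and stay below 1% in the other 4 libraries.

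Of the 37 gene lists tested, 12 passed camera with its preset correlation, 8 higher and 4 lower in AdIGF1RKO. None of the 37 passed with an estimated correlation (the smallest adjusted p = 0.854) or by fry's test of a common direction (the smallest adjusted p = 0.714). No member of any list passed the limma test over all genes. Adjusted over the list alone, 1 gene passed among apelin and angiogenic factors (Apln), 2 among adipokines (Apln and Lep), 2 among mature adipocyte genes (Lep and Dgat2) and 1 among β-catenin targets (Nkd1). The lists around apelin and β-catenin follow the series title and are not independent evidence of its direction. The count of 12 was 8 without Flox 3, 6 without AdIGF1RKO 1 and 11 without AdIGF1RKO 2. It was 8 without both muscle-rich libraries, 5 with array quality weights and 12 with the muscle covariate. These counts mix lists kept with lists gained. Of the 12, 9 were lost without Flox 3 (5 gained), 6 without AdIGF1RKO 1 (0 gained) and 3 without AdIGF1RKO 2 (2 gained). Without both muscle-rich libraries 6 were lost (2 gained), with array quality weights 9 (2 gained) and with the muscle covariate 2 (2 gained).

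Genes of cholesterol synthesis were higher as a list (camera adjusted p = 2.5e-07; adjusted p = 0.854 with an estimated correlation). Of 24 tested genes 23 had a positive log2 difference, with a median of 0.22, and 0 passed the test on their own. Hmgcs1, which makes the precursor of the pathway, had 122 ± 16.9 in Flox and 188 ± 39.6 in AdIGF1RKO, and Sc5d had 69.8 ± 12.3 and 104 ± 23.5. The median deviation of the list from the mean of the 6 libraries was 0.36 in AdIGF1RKO 2 and 0.20 in AdIGF1RKO 3, but -0.20 in AdIGF1RKO 1, within the Flox range of -0.26 to -0.01. The list passed camera without each library in turn, with medians from 0.15 without AdIGF1RKO 2 to 0.45 without AdIGF1RKO 1. With the values as deposited, where the median of tested genes was -0.17, its median was 0.07 and it passed as well.

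De novo lipogenesis genes were higher as a list with 19 of 22 positive and a median of 0.14 (camera adjusted p = 0.0217; adjusted p = 0.893 with an estimated correlation). Without AdIGF1RKO 2, the library with the macrophage genes, the median was -0.04 and the list did not pass (adjusted p = 0.415), and without Flox 2 the median was 0.05 and it did not pass either (adjusted p = 0.430). Scd1, a desaturase, had 9446 ± 1140 in Flox and 12348 ± 1796 in AdIGF1RKO, while Acacb, the acetyl-CoA carboxylase linked to control of fat oxidation, had 47.7 ± 9.70 and 36.3 ± 4.96. Scd2 had 122 ± 21.7 and 187 ± 76.9, and Aacs had 75.3 ± 9.55 and 93.1 ± 17.0. None of these 4 passed the test.

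Vascular and matrix lists were higher in AdIGF1RKO. Of 20 endothelial markers 17 were positive (median 0.15, camera adjusted p = 0.000137), as were 22 of 33 extracellular matrix genes (median 0.14, camera adjusted p = 0.000125) and 10 of 15 apelin and angiogenic factors (median 0.14, camera adjusted p = 0.00226). With an estimated correlation each had an adjusted p = 0.854. The endothelial examples Erg, with 24.0 ± 2.28 in Flox and 29.1 ± 2.05 in AdIGF1RKO, and Robo4, with 24.1 ± 2.12 and 30.5 ± 4.35, did not pass on their own. Neither did Col15a1, a basement membrane collagen with 214 ± 19.1 and 292 ± 26.0, Col4a2 with 180 ± 17.3 and 223 ± 20.9, or the placental growth factor gene Pgf with 3.70 ± 0.650 and 6.84 ± 1.40. These lists were lowest in Flox 3, the library richest in muscle RNA. Without Flox 3 none of the 3 passed, with medians of 0.09 for endothelial markers, 0.05 for matrix and 0.06 for the angiogenic factors and adjusted p-values of 0.238, 0.270 and 0.177. Without AdIGF1RKO 1, the library with the least muscle RNA, endothelial markers (median 0.06, adjusted p = 0.135) and matrix (median 0.10, adjusted p = 0.135) did not pass, while the angiogenic factors passed. With the muscle covariate all 3 passed, with medians of 0.10, 0.08 and 0.09 and adjusted p-values of 0.00799, 0.0312 and 0.00863. Without both muscle-rich libraries the angiogenic factors did not pass (median 0.05, adjusted p = 0.0610), and the other two lists did. With the values as deposited all 3 passed as higher than other genes, with medians of -0.01 for endothelial markers, -0.02 for matrix and 0.02 for angiogenic factors against -0.17 for all tested genes.

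Proliferation genes were higher as a list, with 17 of 21 positive and a median of 0.27 (camera adjusted p = 0.000309; adjusted p = 0.854 with an estimated correlation). Ccnb2 had 1.23 ± 0.506 in Flox and 2.58 ± 0.890 in AdIGF1RKO, and Bub1b had 1.52 ± 0.193 and 2.44 ± 0.703, and neither passed. Without AdIGF1RKO 2 the median was 0.05 and the list did not pass (adjusted p = 0.134), and without Flox 3 it was 0.16 (adjusted p = 0.0502). Adipokines (14 of 22 positive, median 0.12, camera adjusted p = 0.0271) and the unfolded protein response (16 of 24 positive, median 0.06, camera adjusted p = 0.0476) also passed, with an adjusted p = 0.854 each under an estimated correlation. Cfd, the adipokine adipsin, went the other way within its list, with 17076 ± 2749 in Flox and 12768 ± 2676 in AdIGF1RKO. Trib3 had 4.15 ± 0.406 and 5.94 ± 0.324, and Edem1 had 55.7 ± 6.37 and 68.1 ± 6.27. Without Flox 3 the adjusted p was 0.657 for adipokines (median 0.02) and 0.752 for the unfolded protein response (median -0.01). Without AdIGF1RKO 1 it was 0.166 and 0.211, and with the muscle covariate it was 0.162 and 0.363. Without AdIGF1RKO 2 the unfolded protein response did not pass (median -0.01, adjusted p = 0.290), while adipokines passed (median 0.09, adjusted p = 0.019). With the values as deposited adipokines passed as higher than other genes (median -0.04, adjusted p = 0.00304) and the unfolded protein response did not pass (-0.10, adjusted p = 0.376).

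Lists of energy metabolism and protein synthesis were lower. All 50 genes of oxidative phosphorylation had a negative log2 difference, with a median of -0.19 (camera adjusted p = 2.5e-06; adjusted p = 0.854 with an estimated correlation), and the groups overlapped for each of them. Ndufa1 had 751 ± 183 in Flox and 591 ± 80.1 in AdIGF1RKO, and Uqcrc2 had 323 ± 73.5 and 259 ± 30.3. All 15 heat shock genes were negative (median -0.19, camera adjusted p = 0.00428), among them Hspa1b with 76.6 ± 32.2 and 47.2 ± 28.4 and Hspb1 with 294 ± 100.3 and 217 ± 21.2. Both lists were highest in Flox 3, and without that library the medians were 0.02 (adjusted p = 0.960) and -0.01 (adjusted p = 0.839). Without AdIGF1RKO 1 the oxidative phosphorylation median was -0.10 and that list did not pass (adjusted p = 0.135). With array quality weights oxidative phosphorylation (median -0.03, adjusted p = 0.393) and heat shock (median -0.09, adjusted p = 0.159) did not pass. Fatty acid oxidation had 20 of 24 genes negative (median -0.09, camera adjusted p = 0.00678), with Eci1 at 205 ± 5.91 and 176 ± 5.13 and Slc25a20, the carnitine carrier, at 79.4 ± 7.66 and 67.7 ± 1.89. Cytosolic ribosome had 30 of 36 negative (median -0.08, camera adjusted p = 0.00618), with Rpl5 at 43.8 ± 3.76 and 38.2 ± 2.10 and Rps3 at 1085 ± 47.7 and 966 ± 19.1. With an estimated correlation heat shock, fatty acid oxidation and ribosome each had an adjusted p = 0.854. With the replicate number as a block the last 2 lists did not pass (adjusted p = 0.0536 and 0.0753). Fatty acid oxidation also did not pass without Flox 1 (adjusted p = 0.0762) or without AdIGF1RKO 3 (adjusted p = 0.115), and ribosome did not pass without Flox 1 (adjusted p = 0.0637), without Flox 3 (median -0.05, adjusted p = 0.107) or without AdIGF1RKO 1 (median -0.05, adjusted p = 0.135). Heat shock did not pass without AdIGF1RKO 3 (adjusted p = 0.1003). With libraries scaled to equal sums the medians of fatty acid oxidation and ribosome were 0.03 and 0.04, and neither passed. Both were also lost with quantile normalization (medians -0.04 and 0.01, adjusted p = 0.157 and 0.924). Without both muscle-rich libraries fatty acid oxidation (adjusted p = 0.196), ribosome (adjusted p = 0.235) and heat shock (median 0.01, adjusted p = 0.687) did not pass.

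**Figure D3:**
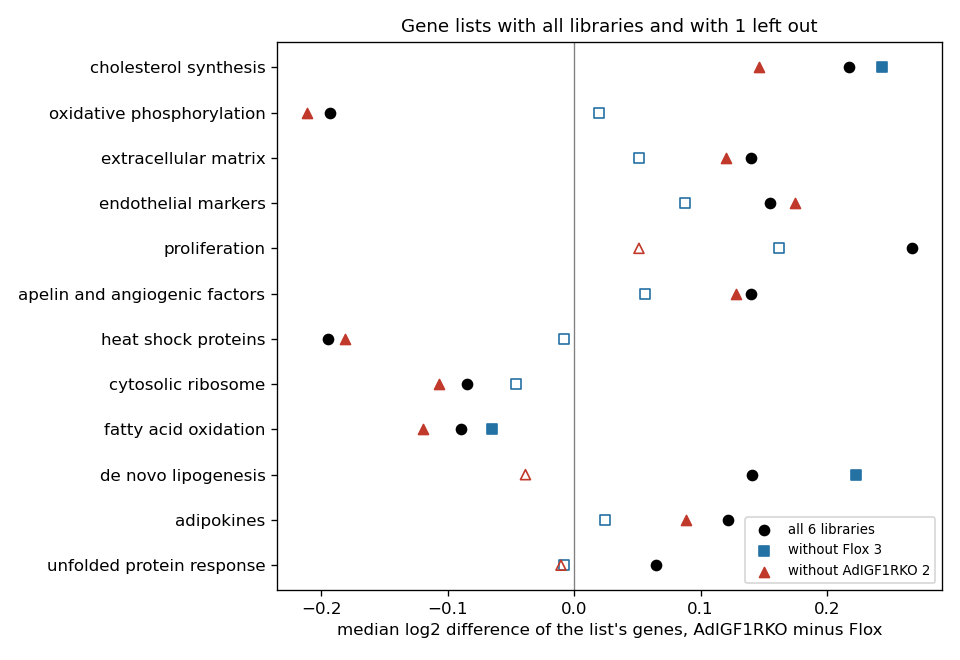
Median log2 difference (AdIGF1RKO minus Flox, horizontal axis) of the 12 gene lists that passed camera with its preset correlation, from all 6 libraries (circles), without Flox 3 (squares) and without AdIGF1RKO 2 (triangles); filled symbols passed at an adjusted p under 0.05 and open symbols did not. Without Flox 3 the oxidative phosphorylation median is 0.02, against -0.19 with all libraries.

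The signalling lists in this paragraph did not pass in the main fit, unlike the apelin and angiogenic factors given above. β-catenin targets had 8 of 14 genes positive and a median of 0.05 (camera adjusted p = 0.0868). This list passed with no filter (median 0.09, adjusted p = 0.0138), with a mean of at least 5 (0.13, adjusted p = 0.0175), without Flox 2 (0.09, adjusted p = 0.0425) and with the values as deposited (-0.08 against -0.17 for tested genes, adjusted p = 0.0144), and it had an adjusted p = 0.854 with an estimated correlation. Nkd1, a Wnt feedback inhibitor, had 6.71 ± 0.651 in Flox and 10.4 ± 0.0678 in AdIGF1RKO, and it passed adjusted over the list alone (adjusted p = 0.0212) but not over all genes by limma, while DESeq2 called it (adjusted p = 0.0324). Apcdd1 had 52.1 ± 20.04 and 74.4 ± 4.84, and Cd44 had 12.7 ± 2.56 and 19.9 ± 8.16. Among Wnt pathway components 16 of 35 were positive (median -0.01, camera adjusted p = 0.865). Lrp6, a Wnt coreceptor, had 58.2 ± 1.16 and 50.2 ± 2.22, and Rspo1 had 3.76 ± 0.597 and 2.72 ± 0.0473. The insulin and IGF pathway had 11 of 25 positive (median -0.04, adjusted p = 0.960), FoxO targets 7 of 22 (median -0.09, adjusted p = 0.402) and growth hormone response 4 of 10 (median -0.07, adjusted p = 0.969). Thermogenic adipocyte genes had 11 of 25 positive (median -0.08, adjusted p = 0.750), creatine and calcium cycling 4 of 9 (median -0.14, adjusted p = 0.836), mature adipocyte genes 13 of 25 (median 0.04, adjusted p = 0.392) and lipolysis 10 of 21 (median -0.02, adjusted p = 0.392). Mature adipocyte genes passed with quantile normalization (adjusted p = 0.0376), without Flox 2 (adjusted p = 0.0358) and without AdIGF1RKO 2 (adjusted p = 0.0417), and lipolysis without Flox 2 (adjusted p = 0.0496). Dgat2, which makes triglyceride, had 594 ± 41.7 and 1021 ± 217, passed adjusted over the mature adipocyte list alone (adjusted p = 0.0477) and was called by DESeq2 (adjusted p = 0.0167). Dgat1, with the same reaction, had 185 ± 14.8 and 153 ± 15.7 and did not pass. Ucp1 was not analysed here.

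Cell type and stress lists that did not pass were inflammatory cytokines (median 0.10, adjusted p = 0.0566), macrophage markers (median 0.12, adjusted p = 0.392), T and NK cell markers (median 0.06, adjusted p = 0.467), neutrophil and mast cell markers (median -0.02, adjusted p = 0.751) and adipocyte progenitor markers (median -0.01, adjusted p = 0.998). Macrophage markers passed as higher without AdIGF1RKO 3 (median 0.22, adjusted p = 0.00442) and without Flox 1 (0.16, adjusted p = 0.0192), and as lower without Flox 3 (-0.09, adjusted p = 0.0214). Inflammatory cytokines passed as higher with the replicate number as a block (adjusted p = 0.0480), with no filter (adjusted p = 0.0408), without the intensity trend (adjusted p = 0.0476), with the values as deposited (adjusted p = 0.00304), without Flox 1 (median 0.21, adjusted p = 0.000308), without Flox 2 (adjusted p = 0.0387) and without AdIGF1RKO 3 (adjusted p = 0.0194). Their median was -0.04 without Flox 3 (adjusted p = 0.507) and -0.02 without AdIGF1RKO 2 (adjusted p = 0.370), the library with high Spp1, a member of the list. It was -0.01 without both muscle-rich libraries (adjusted p = 0.986) and -0.03 with array quality weights (adjusted p = 0.534). T and NK cell markers passed as higher without Flox 1 (0.39, adjusted p = 0.000148) and with the values as deposited (-0.05, adjusted p = 0.00604). They passed as lower with array quality weights (-0.45, adjusted p = 0.0356). B cell and lymph node markers passed as lower with those weights (-0.31, adjusted p = 0.034) and without both muscle-rich libraries (-0.21, adjusted p = 0.0466). Mammary and skin epithelium markers passed as higher without AdIGF1RKO 3 (0.23, adjusted p = 0.0251) and as deposited (0.10, adjusted p = 0.0016). Mural and smooth muscle markers had a median of -0.03 (adjusted p = 0.831), nerve and Schwann cell markers -0.05 (adjusted p = 0.430), and mammary and skin epithelium markers 0.24 (adjusted p = 0.0661). The glucocorticoid response had a median of -0.09 (adjusted p = 0.133), the circadian clock -0.16 (adjusted p = 0.153), the hypoxia response -0.14 (adjusted p = 0.392) and immediate early genes -0.03 (adjusted p = 0.831). The glucocorticoid response passed as lower without AdIGF1RKO 2 (median -0.23, adjusted p = 0.00257), without Flox 3 (-0.21, adjusted p = 0.0214) and with the muscle covariate (-0.15, adjusted p = 0.0111), and immediate early genes did so without Flox 3 (-0.22, adjusted p = 0.0214) and with the covariate (-0.19, adjusted p = 0.00476). Without Flox 3 B cell and lymph node markers (-0.27, adjusted p = 0.0214) and interferon-stimulated genes (-0.08, adjusted p = 0.0378) passed as lower, and without Flox 2 interferon-stimulated genes passed as higher (0.17, adjusted p = 0.000645) and the circadian clock as lower (-0.15, adjusted p = 0.00617). Mammary and skin epithelium markers (0.36, adjusted p = 0.00477) passed as higher and nerve and Schwann cell markers (-0.22, adjusted p = 0.00636) as lower without Flox 1. Interferon-stimulated genes had a median of 0.03 (adjusted p = 0.605) and lysosome and autophagy genes 0.01 (adjusted p = 0.750). B cell and lymph node markers had a median of -0.11 (adjusted p = 0.421), and fry's test for changes in either direction gave an adjusted p = 0.00915, the smallest of the 37 lists. Cd79b of that list had 1.601 ± 0.300 and 2.94 ± 0.104, and Igkc had 294 ± 69.0 and 195 ± 55.0. That fry test gave an adjusted p = 0.0317 for apelin and angiogenic factors, the only other list below the threshold. The camera direction was upward while the median was negative for lipolysis, neutrophil and mast cell, mural and smooth muscle, creatine and calcium cycling, and insulin and IGF lists. For lysosome and autophagy the mean was negative with a positive median. Erythroid markers, with 4 tested genes, mesothelial markers, with 3, and mitochondrially encoded genes, with 0, had too few genes for a list test.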

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

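Alternatives named below as edgeR, DESeq2, the muscle covariate and the omission of both muscle-rich libraries were chosen after seeing the data. Of 24 alternatives for the number of genes changed, 21 gave 0, as did the original. The others were DESeq2 with 23, the unadjusted p under 0.05 with 385, and the omission of Flox 1 with 1 (the range over single omissions is 0 to 1). The replicate block gave 0 genes and 12 lists; it took fatty acid oxidation and cytosolic ribosome out of the called lists and brought skeletal muscle markers and inflammatory cytokines in, and it changed no other call among the results compared here. The log2 difference of Igf1r stayed negative and short of the threshold under all its alternatives, from -0.33 as deposited to -0.08 with libraries scaled to equal sums. The number of lists past the threshold went from 12 to 5 with array quality weights, where 9 of the 12 were lost and 2 others gained. It was 0 with an estimated correlation and 0 with fry. When a library was left out it lay between 6 (without AdIGF1RKO 1) and 18 (without Flox 2, with 1 lost and 7 gained). For the named genes other than Igf1r, 552 of 566 values kept their direction and their side of the threshold, 13 passed only with DESeq2, and Ctnnb1 changed sign as deposited (-0.0089), a scaling that lowers the median of all tested genes to -0.17. The cause of the other shifts was not tested.

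Among the 20 lists followed, 27 values changed direction by camera and 1 by fry; camera ranks a list against other genes, so its direction can turn while the median does not. As deposited these were Wnt components (median -0.16), insulin and IGF (-0.20), thermogenic (-0.24) and skeletal muscle (-1.63). With array weights it was macrophage markers (-0.18), and by fry insulin and IGF (-0.0393). With the muscle covariate they were insulin and IGF (-0.0417), thermogenic (-0.05) and macrophage markers (0.0496). Without both muscle-rich libraries they were heat shock (0.0067), insulin and IGF (-0.0176), thermogenic (0.0303), mature adipocyte (-0.037) and macrophage markers (0.10). Leaving out single libraries moved the medians from -0.345 to 0.0195 for oxidative phosphorylation, -0.0384 to 0.356 for de novo lipogenesis, -0.101 to 0.0152 for Wnt components, -0.0607 to 0.0293 for insulin and IGF, -0.138 to 0.0483 for thermogenic, -0.11 to 0.22 for macrophage and -3.20 to 0.34 for skeletal muscle genes. The cause was not tested for these lists, except for oxidative phosphorylation. With 3 libraries per group and this spread, the simulated changes of a log2 size of 1 were mostly missed, so differences of that size were not reliably detectable here.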

Other observations

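The tests of muscle RNA and of the major urinary protein genes were chosen after the result was seen; the counts over splits and the tests of neighbouring genes were set out before their results were seen.

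Aldh1a7, an aldehyde dehydrogenase gene singled out after its values were seen, was the gene limma called when Flox 1 was left out. It had 70.7 scaled CPM in Flox 1, 6.64 in Flox 2 and 5.37 in Flox 3, against 71.2, 95.0 and 69.7 in the AdIGF1RKO libraries. Flox 1 thus had the level of the AdIGF1RKO libraries for this gene. Other genes called by DESeq2 included Prr32, Cdr2, Adamts5, Dtx4, Jpt2, Rimklb, Mup14 and Mup2. Rimklb had 0.468 ± 0.158 scaled CPM in Flox and 2.94 ± 2.28 in AdIGF1RKO, and Adamts5, a matrix protease, had 34.4 ± 3.97 and 54.1 ± 7.03. The Y-linked genes Ddx3y, Uty and Kdm5d were read in all 6 libraries, each with at least 530 reads.

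The 385 genes at an unadjusted p under 0.05 and the 12 lists past the threshold were compared with all 10 splits of the 6 libraries into 3 and 3. As many genes were found in 5 of the 10 splits, the real one included, with 1554 as the highest of the others, and as many lists in 6 of the 10, with 17 as the highest of the others. These splits are too few for a share under 0.05. The split with 1554 genes set Flox 1, Flox 2 and AdIGF1RKO 1 against the rest. It was picked as the highest and gave 0 genes at an adjusted p under 0.05. Whether a structure of the samples other than genotype lies behind it was not tested. Of the splits that part all 3 same-numbered pairs, the other 3 gave 161, 326 and 362 genes and 3, 11 and 17 lists.

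Oxidative phosphorylation genes were lower and cholesterol synthesis genes higher as lists, while the libraries differed in skeletal muscle RNA. With the muscle score as a covariate the oxidative phosphorylation median kept 43.2% of its size, moving from -0.19 to -0.08, without Flox 3 it was 0.02, and without AdIGF1RKO 1, the library with the least muscle RNA, it was -0.10 and the list did not pass (adjusted p = 0.135). Differences in muscle RNA are therefore a candidate explanation for that list's difference, in part or in whole. The list still passed camera with the covariate and the preset correlation (adjusted p = 0.00426). That pass cannot show a remainder beyond muscle RNA, since the estimated inter-gene correlation of the list was 0.84, well above the preset one. Without the covariate, the list did not pass with an estimated correlation (adjusted p = 0.854). Whether any of its difference is separate from muscle RNA stays open. The cholesterol synthesis median kept 140% of its size with the covariate, at 0.31 (camera adjusted p = 1.9e-10). This argues against muscle RNA as its whole source. The cholesterol synthesis median was 0.15 without both muscle-rich libraries (camera adjusted p = 0.00119). That omission did not level the muscle RNA, since the median of the muscle markers was still -1.41. Whether genotype or differences between these few animals account for the cholesterol list stays open, since it was lost with an estimated correlation.

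The major urinary protein genes were lower in AdIGF1RKO, with 12 of 15 genes lower without overlap of the groups, against 501 of all 12993 tested genes. Since they are near-identical copies, the 12 genes are not separate observations. Summed over these 15 genes, which removes the division of reads among them but not with any other copies, Flox had 4475 ± 2706 scaled CPM and AdIGF1RKO 1477 ± 281. The difference of the mean log2 sums was -1.45 (exact permutation p = 0.1, two-sided, over all splits of 3 against 3). With exchanges only within same-numbered pairs the permutation p was 0.25, and each is the smallest possible. Mup11, Mup18 and Mup22 had been named for groups that do not overlap, so these p-values are not independent support. The lower sum argues against a different division of reads among these 15 paralogs as the whole source. Flox 3 had the highest sum, at 7575, and without it the log2 difference was -0.99, so the difference did not rest on that library alone. Because Mup11, Mup18 and Mup22 were named for lower values in every AdIGF1RKO library, a lower sum without Flox 3 was largely fixed in advance. The absence of overlap adds nothing here, since all 3 AdIGF1RKO sums already lay below all 3 Flox sums. The difference of the sums was -1.62 with the values as deposited and -1.33 with libraries scaled to equal sums. An effect of Igf1r loss stays open, as do other differences between the animals, and neither was tested.

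Rfc4 (10.3 ± 1.41 scaled CPM in Flox and 15.9 ± 1.48 in AdIGF1RKO) neighbours Adipoq, the gene whose promoter drives Cre, and was singled out after its values were seen. The hypothesis that the Adipoq-Cre transgene carries extra copies of genes next to Adipoq was tested on the other 5 of the 3 nearest tested genes on each side. Of these, 0 were higher in all 3 AdIGF1RKO libraries at an unadjusted p under 0.05, their median log2 difference was 0.01 (percentile 67.1 of 12437 such windows), and Eif4a2 had the largest difference, 0.20. Only 9.70% of all such windows held a neighbour of that kind, so a count of 0 decides little. The same test around Zfp949, for an effect on its neighbourhood, also gave 0 of 6 genes higher, with a median of 0.00 (percentile 63.2); Mthfsl (-0.41, unadjusted p = 0.0471) and Snx14 (-0.15, unadjusted p = 0.166) were lower without overlap, and Bcl2a1a was at 0.60 with overlap (unadjusted p = 0.0508). A transgene could hold fewer genes than these windows, so a copy of Rfc4 alone may not be told from chance here, and a regional effect around Zfp949 stays open as well. Neighbours were taken from a RefSeq gene table of the assembly GRCm38.p6, in which 12561 of the tested symbols, 96.7%, were found.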
